A study of Mus musculus with 15 samples.

How the data were processed

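Chromatin immunoprecipitation with sequencing (ChIP-seq) measured 2 features of mouse T helper 17 (Th17) cells: acetylation of lysine 9 of histone H3 (H3K9ac), a mark of active promoters and enhancers, and binding of PCAF, a histone acetyltransferase encoded by Kat2b. Per the labels' protocols, spleen cells were cultured with antibodies to CD3 and CD28 and with IL-6, IL-1β and IL-23, and were collected on day 4. They were fixed for 10 min in 1% formaldehyde before sonication. The series lists 15 libraries. Of these, 9 are immunoprecipitated libraries with a peak list, and 6 are input libraries that were not analysed here.

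The titles name 2 experiments. Experiment 1 holds H3K9ac and PCAF libraries of cells given PBS, Activin-A, or Activin-A with dorsomorphin, an inhibitor of the AMP-activated protein kinase AMPK. Experiment 2 holds H3K9ac libraries of cells given PBS or Activin-A, and of Prkaa1 knockout cells given Activin-A. Prkaa1 encodes a catalytic subunit of AMPK. Only H3K9ac with PBS and with Activin-A was measured in both experiments, so each of those groups had n = 2 and every other group 1 library. The labels do not say whether the 2 experiments used separate animals, so a p-value measures only the spread between these libraries.

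Per the submitters' processing notes, FastQC, Bowtie2, SAMtools, bedtools and MACS2 were used with the mouse build mm10, and neither the versions nor the settings are given in the sources used here. The authors deposited 1 peak list per library, not pooled over libraries, with 3 columns holding chromosome, start and end. The deposited positions are whole numbers of bases and not read counts. The lists hold no score, height, p-value or read depth, so the sequencing depth is unknown and the strength of a peak could only be judged by its width. Peaks lay on 20 chromosomes (19 autosomes and X). The smallest gap between neighbouring H3K9ac peaks was 962 and 982 bp in the PBS and Activin-A libraries of experiment 1. It was 301 bp in the dorsomorphin library and 406 bp in all 3 libraries of experiment 2, so neighbouring peaks had not been joined alike before deposit.

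Peak lists were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlaps were checked against bedtools 2.31.1. Intervals that shared at least 1 bp counted as overlapping. The peaks of all 6 H3K9ac libraries were merged into regions. A region is called lost when both PBS libraries held a peak there and neither Activin-A library did, and gained in the reverse case. Within 1 experiment the same words describe 1 library against another. Shares carry Wilson 95% intervals, which cover counting error only and not the difference between cultures. Peak number, covered length and median width were compared by a two-sided exact permutation test. With 2 libraries against 2 its smallest possible p is 0.333, so it cannot pass a threshold of 0.05. Comparisons with 1 library per arm have no replicate check and carry no p-value. Positions of PCAF peaks were set against 1000 circular shifts along each chromosome.

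Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 is built on, with 21631 protein-coding genes and no strand. A promoter could therefore not be told from the other end of a gene. A gene was called marked when a peak lay within 1000 bp of either annotated end, in place of the start sites chosen before the data were examined. In a further count, chosen after the data were seen, a gene counted as lost or gained only if no peak at its ends overlapped any peak of the other arm. For many genes only the edge of a shared peak had crossed the window. The 20 gene lists, holding 386 distinct genes of which 383 were found, were fixed before the data were examined. They covered pathogenic, non-pathogenic and core Th17 genes, the adenosine and AMPK pathways, glycolysis, the TCA cycle, fatty acid oxidation, acetyl-CoA and lipid synthesis, histone acetyltransferases and deacetylases, and activin and TGF-β signalling. The others were regulatory T cell, Th1, Th2, B cell, myeloid cell, CD8 T cell and NK cell, erythroid, housekeeping and neuronal genes. The count of changed genes in a list was placed among 10000 random lists of the same size, matched on peak width in 10 bins. Because genes are not replicates, such a percentile describes these libraries only.

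Named genes followed a rule fixed before the data were examined. It took 24 panel genes, up to 4 changed members per list and direction, and the 10 lost and 5 gained genes with the widest peaks, up to 30 genes per comparison, and some genes that it names are not reported here. Most of the widest lost and gained H3K9ac genes, and some PCAF genes, turned out to be edge crossings. The next in rank without an overlapping peak are named instead, chosen after their values were seen. So are Il4, Stat4, Il18r1, Nkg7, Hdac9, Acvr2a, Skil, Pax6, Dlx2, the widest H3K9ac domains and the loci of smallest p, and Fasl and Kat6b in the model of covered length.

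A model of covered length was added after the data were seen. For each gene body with 10 kb on each side, the base pairs covered by H3K9ac peaks were summed per library, and log2(covered length + 500 bp), centred on the median locus of each library, was compared between the 2 PBS and 2 Activin-A libraries with limma 3.58.1 in R 4.3.3. It used the 14895 loci covered in at least 2 libraries. Fold changes are on that log2 scale, which understates changes at sparsely covered loci. They are relative to the median locus, which before centring differed between Activin-A and PBS by 0.02 in experiment 1 and by -0.13 in experiment 2, and between dorsomorphin and Activin-A by -0.32. Lists were tested with camera, part of limma, with a preset correlation of 0.01 and again with an estimated correlation. All p-values were adjusted by the method of Benjamini and Hochberg over all loci or over the 20 lists. Neighbouring genes share windows, so list members are not independent.

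Region calls, list percentiles and limma at single loci were tested on simulated data, and camera was not. All 200 planted lost and 200 planted gained regions were recovered. Of 200 simulated gene lists with no effect, 18 stood above percentile 95 or below percentile 5. With the spread seen between these libraries, limma recovered 0% of 200 loci changed 2-fold and 83% of 200 loci changed 8-fold, with 4 false calls in the latter case.

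The experiment number pairs the libraries, since the titles give it as the experiment. The difference between the 2 PBS libraries and that between the 2 Activin-A libraries correlated across the 14895 loci (Pearson r = 0.410, Spearman rho = 0.375), and loci are not independent replicates. The Activin-A minus PBS difference of experiment 1 correlated less with that of experiment 2 (Pearson r = 0.1559, Spearman rho = 0.1155). Alternatives were another overlap rule, the widest peaks, joining within 500 bp or 1100 bp, a minimum width, other gene windows, locus values without centring, random lists without matching, blocking on the experiment and leaving out each library or experiment. Stricter limits on the peak score, set before the data were examined, were not run because the lists hold no score. Width took its place, in the widest 28061 H3K9ac or 4159 PCAF peaks per library and in peaks of at least 500 bp. Figures were drawn with matplotlib 3.10.9.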

Results

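The data comprised 9 peak lists from mouse Th17 cells, the CD4 T cells that secrete IL-17, grown from spleen under conditions that include IL-23. The study's text contrasts cells grown without Activin-A, a TGF-β family cytokine, as pathogenic with cells grown with it as non-pathogenic, and its title places AMPK downstream of an adenosine receptor, the product of Adora2a. The 6 H3K9ac lists held 28061 to 35767 peaks covering 44.0 to 65.0 Mb, and the 3 PCAF lists held 4159 to 10127 peaks covering 2.11 to 5.50 Mb. Between 11988 and 12508 of the 21631 protein-coding genes had an H3K9ac peak within 1000 bp of a gene end. All positions are given on mm10.

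**Figure D1:**
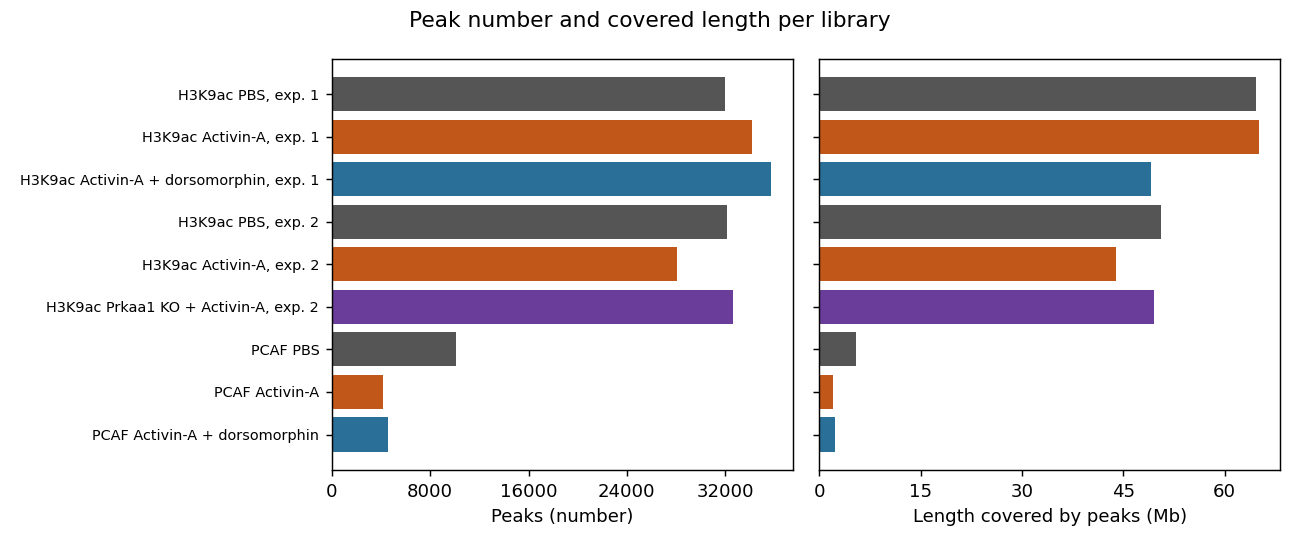
Number of peaks (left, x axis) and length covered by peaks in Mb (right, x axis) in each of the 9 libraries, with 1 bar per library and no error bars. Activin-A went with 2270 more H3K9ac peaks than PBS in experiment 1 and with fewer in experiment 2, and PCAF peaks numbered 10127 with PBS against 4159 and 4534 with Activin-A.

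Prkaa1, the gene disrupted in the knockout library (chromosome 15, 5143861 to 5181899), had an H3K9ac peak at the same gene end in all 6 libraries. Its width was 1735 bp in the knockout and between 2261 and 2656 bp in the other 5. A peak at a gene end does not show whether the coding sequence was deleted, so these lists do not check the genotype.

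The first comparison, the only one with replicates, asked how H3K9ac differed between cells grown with PBS and with Activin-A. The signature cytokine genes Il17a (chromosome 1, 20730905 to 20734496) and Il17f (chromosome 1, 20777146 to 20785274) had no H3K9ac peak within 10 kb in either PBS library and had peaks in both Activin-A libraries. Peaks covered 1098 and 1849 bp around Il17a with Activin-A, and 2911 and 1614 bp around Il17f. Over all gene loci, 26 were covered in both Activin-A libraries and neither PBS library, and 94 the reverse. The split of PBS 1 and Activin-A 2 against PBS 2 and Activin-A 1 gave 10 and 79. Experiment 1 against experiment 2 gave 164 and 79, so such a pattern by itself does not single out the treatment. The log2 difference was 2.01 ± 0.53 for Il17a and 2.48 ± 0.43 for Il17f (SE, n = 2 per group). The PBS libraries held 0 bp at these 2 loci, so their values differed only by the centring. Nt5e, which encodes the adenosine-producing enzyme CD73 (chromosome 9, 88327609 to 88372089), was covered over 3132 and 777 bp with PBS and 7681 and 3693 bp with Activin-A, which gave log2 differences relative to the median locus of 1.15 and 1.85 in the 2 experiments. Rora and Ahr, which encode transcription factors expressed in Th17 cells, were covered further with Activin-A in both experiments, with differences of 0.58 ± 0.22 and 0.79 ± 0.31. None of these differences passed the test (limma, adjusted p = 0.879 for Il17a, 0.577 for Il17f, 0.879 for Nt5e and 1.00 for Rora and Ahr). With the experiment as a block none passed either (limma, adjusted p = 0.504 for Il17a, Il17f, Nt5e and Ahr, and 0.577 for Rora).

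Other effector genes had less H3K9ac with Activin-A in both experiments, again without passing the test. Tbx21, which encodes the Th1 regulator T-bet (chromosome 11, 97098007 to 97115331), was covered over 14864 and 11099 bp with PBS and 8620 and 3615 bp with Activin-A (log2 difference -1.07 ± 0.25, limma adjusted p = 0.879). The difference was -1.07 ± 0.39 for Csf2, which encodes the cytokine GM-CSF, and -1.77 ± 0.59 for Il10, which encodes the anti-inflammatory cytokine IL-10 (both adjusted p = 1.00). At Il10 (chromosome 1, 131019845 to 131024970) the PBS libraries held 1698 and 3247 bp of peaks, Activin-A held 0 and 808 bp, and the latter lay within the gene body. Il22 had no peak within 10 kb in any H3K9ac library, and Ifng had a single peak of 485 bp, in the Activin-A library of experiment 1. The other panel genes reported here lay between -0.49 (Il23r) and 0.79 (Maf), all with adjusted p = 1.00. With the experiment as a block, adjusted p was 0.504 for Tbx21 and Il10, 0.606 for Csf2 and 0.554 for Maf (limma).

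**Figure D2:**
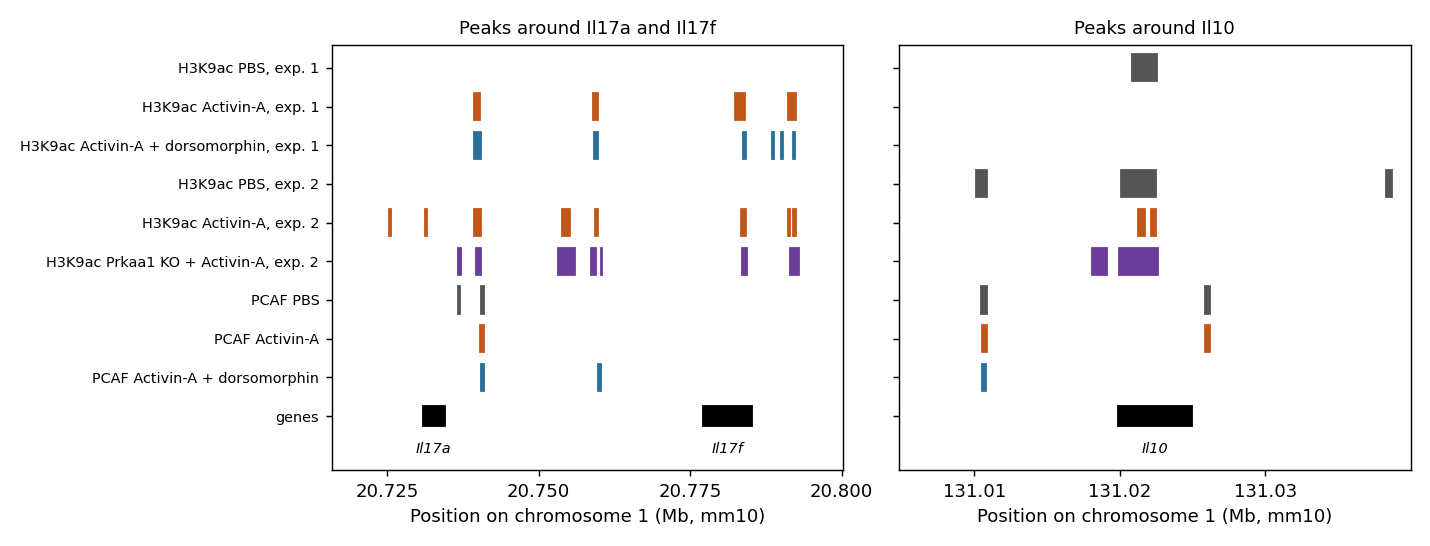
Peaks of the 9 libraries, 1 line each, along chromosome 1 (x axis, position in Mb on mm10) around Il17a and Il17f (left) and Il10 (right), with gene bodies in black and colours marking the treatment. Around Il17a and Il17f the PBS libraries show no H3K9ac peak, and at Il10 the Activin-A and dorsomorphin libraries of experiment 1 show none.

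Across 14895 loci limma called 0 lower and 0 higher with Activin-A. At an unadjusted p under 0.05 there were 343 lower and 220 higher loci, 563 in all against 744.8 that chance alone gives. Without centring on the median locus the calls were again 0 and 0, with 191 lower and 56 higher loci at an unadjusted p under 0.05. The smallest adjusted p was 0.0613, for Osr2 (-2.24 ± 0.26), followed by Myo3b (2.32 ± 0.35, adjusted p = 0.336), and by Crtam (-1.87 ± 0.32) and Klre1 (1.79 ± 0.32), both with adjusted p = 0.577. With the experiment as a block the counts were again 0 and 0, with a smallest adjusted p of 0.504, while 701 lower and 495 higher loci had an unadjusted p under 0.05, 1196 in all and so more than chance alone gives. Leaving out 1 library called 36 lower and 15 higher loci without PBS 1, 57 and 21 without PBS 2, 153 and 36 without Activin-A 1, and 21 and 26 without Activin-A 2. Those fits assume that the lone library of an arm varies like the other pair.

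By gene list, core Th17 loci were further covered with Activin-A at 14 of 19 members, and Th1 loci less covered at 14 of 17. Both lists passed camera (adjusted p = 0.00392 each, and 0.524 each with an estimated correlation). With p adjusted over the list alone, 2 core Th17 loci passed, Il17a and Il17f, and 2 Th1 loci, Tbx21 and, in the opposite direction, Il18r1 (1.17 ± 0.34), which encodes a chain of the IL-18 receptor. Fasl, a death receptor ligand gene (-1.61 ± 0.63), and Stat4, a gene of IL-12 signalling (-0.49 ± 0.22), were among the less covered Th1 loci without passing. Th2 loci were less covered at 12 of 17 members (camera, adjusted p = 0.0104, and 0.629 with an estimated correlation), with Il13 at -1.56 ± 0.40, Il5 at -1.31 ± 0.55 and Gata3 at -0.55 ± 0.24, of which Il13 passed with p adjusted over the list alone. Neuronal genes, markers of another tissue, were less covered at 7 of 10 members (adjusted p = 0.0309, and 0.524 with an estimated correlation), among them Pax6 (-1.10 ± 0.31) and Dlx2 (-0.94 ± 0.31), of which Pax6 passed with p adjusted over the list alone. Blocking on the experiment ended that call (adjusted p = 0.105).

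Histone acetyltransferase and deacetylase loci were further covered at 24 of 32 members (camera, adjusted p = 0.0434, and 0.524 with an estimated correlation). Among them Kat6b stood at 0.70 ± 0.24 and Hdac9 at -1.79 ± 0.60. Activin and TGF-β signalling loci were further covered at 18 of 25 members, including the activin receptor gene Acvr2a (0.68 ± 0.26) and Skil (0.63 ± 0.24), with a camera adjusted p of 0.0466, or 0.629 with an estimated correlation. Blocking on the experiment (adjusted p = 0.0501) or leaving out the centring (adjusted p = 0.120) ended that call. Neither list had a member past the threshold with p adjusted over the list alone.

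Pathogenic Th17 loci were less covered at 13 of 20 members and non-pathogenic Th17 loci further covered at 13 of 18, and neither list passed (camera, adjusted p = 0.0952 and 0.101). With p adjusted over the list alone 1 locus passed in each, Tbx21 and Nt5e. The pathogenic list shares members with the Th1 list, including Tbx21, Stat4, Il18r1 and Tnf. The camera adjusted p was 0.541 for the adenosine pathway, 0.900 for the AMPK pathway, 0.965 for glycolysis, 0.256 for the TCA cycle, 0.504 for fatty acid oxidation and 0.461 for acetyl-CoA and lipid synthesis. It was 0.964 for regulatory T cell, 0.504 for B cell, 0.965 for myeloid cell, 0.900 for CD8 T cell and NK cell, 0.504 for erythroid and 0.965 for housekeeping genes. With p adjusted over the list alone 1 adenosine locus passed, again Nt5e, and 1 CD8 and NK cell locus, Nkg7 (-1.03 ± 0.30), and none in the other lists of these 12. Without centring, 2 core Th17 loci and 0 in each other list passed with p adjusted over the list alone. In the AMPK, glycolysis, regulatory T cell, myeloid, CD8 and NK, and housekeeping lists the median, the mean and the direction of the test did not share a sign.

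At gene ends, H3K9ac peaks found in both PBS libraries and in neither Activin-A library marked 5 listed genes, and the reverse held for none. Il13, a Th2 cytokine gene (chromosome 11, 53631323 to 53634702), had peaks of 7573 and 4966 bp at its ends with PBS and none with Activin-A, where peaks farther from the gene covered 1782 and 3954 bp. The neighbouring Th2 cytokine gene Il5 had peaks of 372 and 888 bp with PBS. The third cytokine gene of this cluster, Il4 (gene end at 53618665), kept a gene-end peak in all 6 libraries. In the Activin-A and dorsomorphin libraries of experiment 1 only the edge of its peak reached the window (to 53617677 and 53617695). The contrast of Il4 with Il13 therefore depends on the window. The other members were Il10, Inhbb, which encodes a chain of activin B (802 and 357 bp), and the neuronal gene Tbr1 (296 and 397 bp). Il10 and Il13 kept a peak that overlapped the PBS peak in an Activin-A library. The 2 of 14 marked Th2 genes stood at percentile 99.6 of width-matched random lists (0.15 expected). Of this pair only Il5 had no overlapping peak with Activin-A, and both lie in 1 cluster, which random lists of separate genes do not allow for. The Il5 call also depends on the window. In PBS of experiment 1 its peak ended at 53719930, over 500 bp from the gene end at 53720794. Il10 alone was lost in the non-pathogenic Th17 (1 of 16, percentile 95.8) and regulatory T cell lists (1 of 15, percentile 95.8), Inhbb in activin and TGF-β signalling (1 of 24, percentile 94.2) and Tbr1 in the neuronal list. No member of the other 15 lists was lost.

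Across all protein-coding genes, 108 were lost and 35 gained at gene ends, of which 86 and 26 had no overlapping peak in the other arm. The widest lost peaks without an overlapping peak included those at the TGF-β family ligand gene Gdf6 (1578 and 1984 bp), the Wnt receptor gene Fzd10 (600 and 2560 bp), the homeobox gene Emx2 (1828 and 521 bp), the opioid precursor gene Penk (1712 and 639 bp) and Esm1 (1472 and 980 bp). Cabp2, Slc12a8, Rdh1 and Mn1 were also among the widest. The widest gained peak without an overlapping peak belonged to Gpr15, which encodes a homing receptor of T cells to the colon, with 2835 and 7170 bp with Activin-A. Dedd, Tnfrsf13b, Gap43 and Bcl2l10 followed. The window decided many of these calls. Of the 18 changes that the fixed rule named, 6 remained with a window of 500 bp, 4 with 2000 bp and 1 over the gene body with 10 kb on each side. With the experiment as a block, 21 listed genes were lost and 12 gained. Lost and gained listed genes numbered 8 and 1 without PBS 1, 9 and 1 without PBS 2, 12 and 2 without Activin-A 1, 7 and 8 without Activin-A 2, 16 and 3 without experiment 1, and 11 and 10 without experiment 2.

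Genome-wide, 978 H3K9ac regions were lost in both experiments and 541 gained, of 52490 regions in the union. All 6 libraries shared 17665 regions (33.7%), and 19953 (38.0%) occurred in a single library. The split of experiment 1 against experiment 2 gave 2452 and 735 regions, and the remaining split gave 274 and 773. Of the 22628 regions with a peak in both PBS libraries, 1450 had none with Activin-A in experiment 1 and 3229 in experiment 2. The 978 in both compare with 206.9 for independent losses and with 511.4 once regions were matched on width. Counted with the experiment as a block, in at least 1 experiment and against the direction in none, 11897 regions were lost and 10415 gained. Lost and gained regions numbered 4227 and 1331 without PBS 1, 5925 and 1167 without PBS 2, 3229 and 2212 without Activin-A 1, 1450 and 7328 without Activin-A 2, 7251 and 3276 without experiment 1, and 6671 and 8727 without experiment 2.

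The total of H3K9ac peaks did not move one way. PBS libraries held 32069.5 ± 152 peaks and Activin-A libraries 31146.5 ± 4364 (SD, n = 2 each), a difference of -923 that was smaller than the spread between Activin-A libraries (exact permutation test, two-sided, p = 1.00, smallest possible p = 0.333). The difference was 2270 in experiment 1 and -4116 in experiment 2. Covered length was 57.6 ± 9.94 Mb with PBS and 54.5 ± 14.9 Mb with Activin-A, and median width 1160.0 ± 160 bp and 1138 ± 66.5 bp (SD, n = 2 each, exact permutation p = 1.00 for both). In experiment 1, 21.4% of PBS peaks had no Activin-A peak (95% interval 21.0 to 21.9) and 26.0% of Activin-A peaks had no PBS peak (25.6 to 26.5). In experiment 2 the shares were 28.5% (28.0 to 29.0) and 15.9% (15.4 to 16.3). Unshared peaks were narrow: in the narrowest width quartile of PBS peaks 49.5% and 67.8% lacked an Activin-A peak in experiments 1 and 2, against 0.55% and 1.37% in the widest.

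The next comparison asked whether the AMPK inhibitor dorsomorphin restored H3K9ac in Activin-A-treated cells, with 1 library per arm in experiment 1. No library had dorsomorphin without Activin-A. Restoration therefore cannot be told from an effect of dorsomorphin that is unrelated to Activin-A. Around Il17a and Il17f the dorsomorphin library held peaks of 1097 and 1505 bp in total, against 1098 and 2911 bp with Activin-A alone. Il10 had no H3K9ac peak in either library, and Tbx21 was covered over 6101 bp against 8620 bp. These lengths are not corrected for the lower coverage of the dorsomorphin library. Relative to the median locus, its log2 difference from Activin-A was 0.31 for Il17a, -0.45 for Il17f and -0.15 for Tbx21. Of the listed genes, 12 lost a gene-end peak with dorsomorphin and 2 gained one, or 9 and 1 without an overlapping peak. The chemokine gene Ccl3 had a peak of 1088 bp with Activin-A and of 771 bp with PBS, and none with dorsomorphin. Foxp3, the regulator of regulatory T cells (693 bp), the glycolytic regulator gene Pfkfb4 (1025 bp), the TCA cycle gene Idh2 (433 bp), the adenosine receptor gene Adora3 (391 bp), the Th2-list cytokine gene Il31 (245 bp) and the NK receptor gene Klrk1 (960 bp) also lacked a peak with dorsomorphin. So did Vpreb3 (488 bp) and Gad1 (442 bp). Ccl4, Tnfrsf9 and Ccr4 changed only by the edge of a peak that both libraries shared. Prkag3, which encodes a regulatory subunit of AMPK, had peaks of 600 bp with PBS and 369 bp with dorsomorphin and none with Activin-A, although the Activin-A library of experiment 2 held one of 304 bp, and Fcgr3 changed by a peak edge only.

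Across all genes 557 lost and 188 gained a gene-end peak with dorsomorphin, 438 and 158 without an overlapping peak. The widest such losses were at Sobp (3377 bp), Nanos3 (2660 bp), Osbpl2 (2630 bp), Nemp2 (2524 bp), Dedd (2497 bp) and Cd74 (2292 bp), and the widest gains at Cabp2 (1287 bp), Uts2 (1159 bp) and Cd7 (1129 bp). Of the 6671 regions lost with Activin-A in experiment 1, 18.9% held a peak with dorsomorphin (95% interval 17.9 to 19.8). The share was 18.1% (17.3 to 19.0) of the 8727 gained regions and 88.6% (88.1 to 88.9) of those shared by PBS and Activin-A. Judged at regions lost in experiment 2, which shares no library with this contrast, dorsomorphin held the peak at 33.5% (31.3 to 35.7) of the regions where it and Activin-A differed. That share was 31.3% (28.2 to 34.6) at regions gained there and 35.7% over all regions, and the differences between these shares were not tested. Of the 978 regions lost in both experiments, 33.0% (30.2 to 36.0) held a dorsomorphin peak, against 40.1% (36.1 to 44.3) of the 541 gained regions.

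The same question was put to Prkaa1 knockout cells with Activin-A, again with 1 library per arm, in experiment 2. No knockout library was made without Activin-A, so the same limit holds. At Il10 the knockout library held a gene-end peak of 2683 bp, next to 2449 bp with PBS, where Activin-A held none at the gene end and 2 narrow peaks inside the gene that overlap it. Of 16 listed genes with a gene-end peak in PBS and none with Activin-A in experiment 2, 7 had one in the knockout, among them Gzmb (1294 bp, and 1621 bp with PBS), Fasl (901 and 1644 bp) and Cxcr3 (644 and 1701 bp). These 3 kept gene-end peaks with Activin-A in experiment 1. Of the 7, Hk3 and Epor gained only the edge of a peak. The Activin-A list of experiment 2 was the shortest H3K9ac list (28061 peaks, against 32639 in the knockout). A longer list alone can mark some such genes again, and no share over all genes is given beside 7 of 16. The others of the 16, such as Casp1, Il13, Il5, Inhbb and Tbr1, had none in the knockout, and of the 5 lost in both experiments only Il10 had one. Knockout cells also held peaks at Prf1, the perforin gene (684 bp), Tnfrsf9 (1325 bp), Adora3 (466 bp), Slc29a1, an adenosine transporter gene (350 bp), Pfkfb4 (847 bp), Il31 (491 bp), Cd79b (960 bp) and Blnk (499 bp). Il17f, Hk3 and Epor gained a gene-end peak only by its edge. Il17a lost its gene-end peak of 303 bp, although 2 knockout peaks covering 1244 bp lay within 10 kb. Of these the one of 879 bp overlapped an Activin-A peak and the one of 365 bp did not. Ccr4 (251 bp), Slc29a2 (349 bp), Itgae (256 bp), Map2 (378 bp) and Syn1 (318 bp) also lost their gene-end peaks. At Gata3 only a peak edge moved. In all, 7 listed genes were lost and 15 gained, 6 and 11 without an overlapping peak.

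Over all genes the knockout lost 381 and gained 369 gene-end peaks, 334 and 302 without an overlapping peak. The widest such losses were at Atp6v0d2 (1974 bp), Creb5 (1685 bp), Thbd (1524 bp), Syt17 (1465 bp), Gm42517 (1399 bp) and Bcl11a (1274 bp), and the widest gains at Aldh1l1 (1559 bp), BC147527 (1477 bp) and Shisa7 (1464 bp). Of the 7251 regions lost with Activin-A in experiment 2, 29.6% (28.6 to 30.7) held a knockout peak, against 45.2% (43.5 to 46.9) of 3276 gained and 93.2% (92.8 to 93.5) of shared regions. Of the 978 regions lost in both experiments 27.3% (24.6 to 30.2) held a knockout peak, against 58.8% (54.6 to 62.9) of the 541 gained regions. At regions lost in experiment 1, which shares no library with this contrast, the knockout held the peak at 68.4% (65.5 to 71.2) of the regions where it and Activin-A differed. The share was 72.0% (69.6 to 74.2) at regions gained there and 70.0% over all regions. Across 14895 loci, which are not independent replicates, the knockout difference correlated with the Activin-A difference of the other experiment at a Pearson r of 0.0331 (Spearman rho 0.0349), and the dorsomorphin difference at 0.0720 (rho 0.0650). Restored coverage would go with a negative r.

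**Figure D3:**
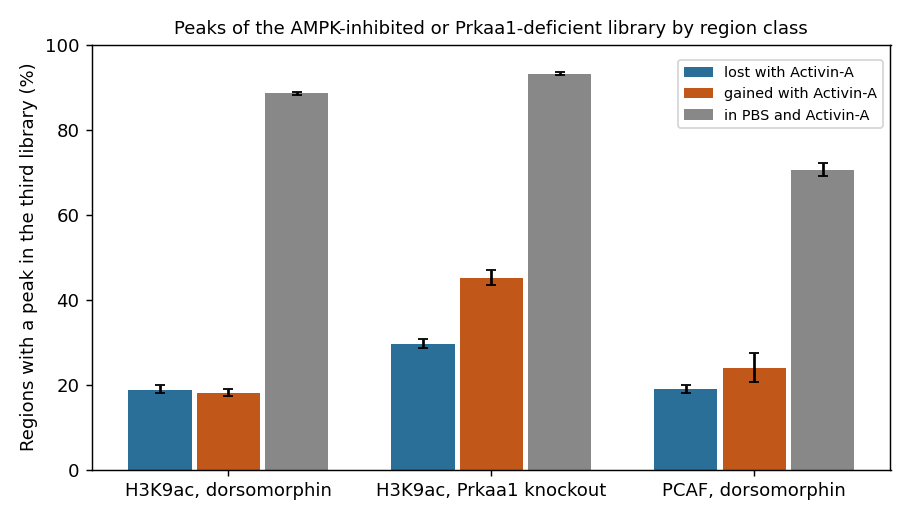
Share of regions (y axis, %) with a peak in the dorsomorphin or knockout library, by whether the region was lost, gained or shared with Activin-A in the same experiment, with Wilson 95% intervals as error bars. Lost and gained regions stand at 18.9% and 18.1% for H3K9ac with dorsomorphin, and gained regions stand above lost regions in the knockout (45.2% against 29.6%).

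PCAF occupancy was compared in experiment 1, with 1 library per arm and no replicate check. The PBS library held 10127 PCAF peaks, 2.44 times the 4159 of the Activin-A library and 2.23 times the 4534 of the dorsomorphin library. Of 4994 genes with a gene-end PCAF peak under PBS, 3147 (63.0%) had none with Activin-A, and 235 genes gained one. Glycolysis genes lost it at 13 of 16 members, where width-matched random lists gave 9.0 (percentile 98.7, or 93.5 without matching). They included Gapdh (1537 bp with PBS), Aldoa (1357 bp), Eno1 (958 bp) and Hk2 (793 bp). TCA cycle genes lost it at 9 of 10 members, with 6.95 expected (percentile 92.3, or 95.8 without matching), including Ogdh (787 bp), Sdhd (569 bp) and Dld (553 bp). Core Th17 genes lost it at 2 of 9 members, Nfkbiz (663 bp) and Batf (488 bp), with 3.78 expected (percentile 11.2, or 0.82 without matching).

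In the other lists the losses were 4 of 8 pathogenic Th17 genes, with Tnf (799 bp) and Gzmb (488 bp), and 3 of 8 non-pathogenic Th17 genes, with Cd69 (589 bp) and Lef1 (573 bp). They were 4 of 8 adenosine pathway genes, led by the adenosine receptor gene Adora2a (992 bp), and 9 of 13 AMPK pathway genes, with Cab39 (666 bp), Foxo3 (653 bp), Sesn2 (631 bp) and the AMPK-activating kinase gene Stk11 (509 bp). Acetyl-CoA and lipid synthesis genes lost 6 of 8, led by the fatty acid synthase gene Fasn (1615 bp), and fatty acid oxidation genes lost 4 of 6, including Etfb (506 bp). Histone acetyltransferase and deacetylase genes lost 6 of 12, with Kat8 (586 bp), and activin and TGF-β signalling genes 9 of 14, with Smurf2 (686 bp), Smad3 (658 bp) and Tgfbr2 (607 bp). Regulatory T cell genes lost 2 of 7, Th1 genes 2 of 6 and Th2 genes 2 of 4, the last including Stat6 (888 bp). Housekeeping genes lost 7 of 15, with 7.33 expected, among them B2m (676 bp) and Tubb5 (675 bp). The only marked B cell gene was kept, the only marked myeloid gene, Cd68 (526 bp), was lost, and no CD8 T cell and NK cell, erythroid or neuronal gene was marked. With width matching, glycolysis alone stood above percentile 95 of the 17 lists with a marked member, and none stood below percentile 5. Since 18 of 200 simulated lists with no effect passed these bounds, 1 list in 17 can do so without an effect. Without matching the TCA cycle alone stood above 95, and core Th17 (0.82) and regulatory T cell genes (4.2) stood below 5. Genes that gained a PCAF peak with Activin-A included Prkaa1 (687 bp), Pdk1 (388 bp), Crebbp and Hdac3 (286 bp each) and Batf3 (1118 bp). A width of 286 bp was the smallest of any peak in that library.

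**Figure D4:**
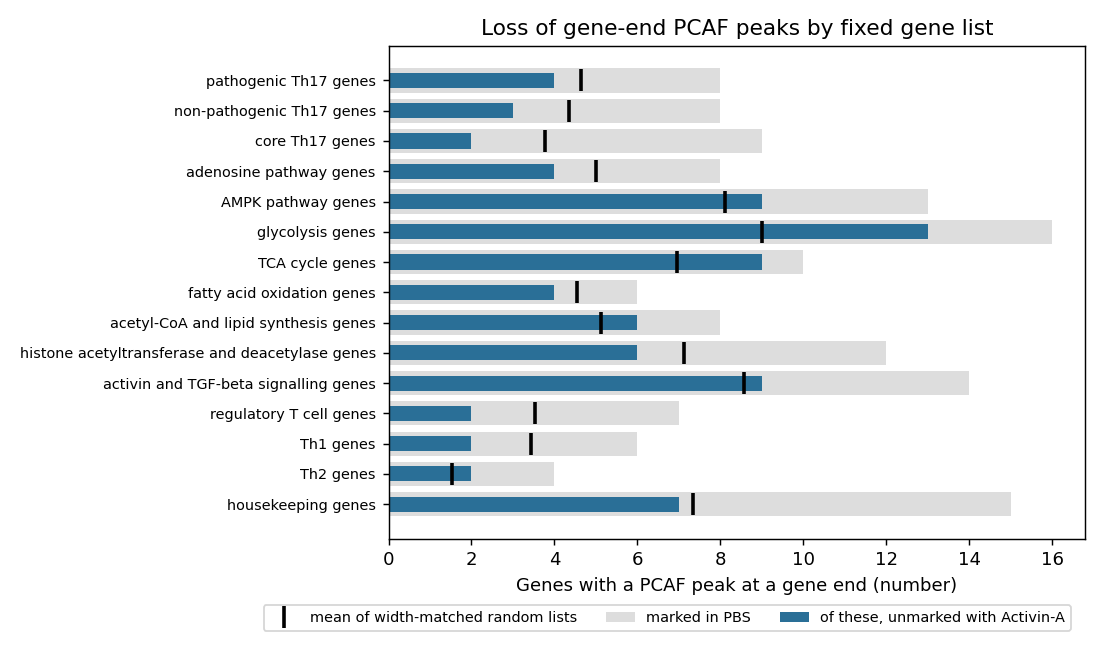
Number of genes (x axis) of each fixed list with a gene-end PCAF peak under PBS (grey bars), those of them without a peak with Activin-A (blue bars) and the mean number of such genes in width-matched random lists (black lines), from 1 library per arm. Glycolysis genes lost the peak at 13 of 16 members against 9.0 expected, and housekeeping genes at 7 of 15 against 7.33.

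The widest PCAF peaks lost with Activin-A without an overlapping peak were at Ms4a6b (3455 bp), Cd53, a leukocyte tetraspanin gene (2523 bp), Gimap5 (2370 bp), St3gal1 (2336 bp) and Atxn1 (2191 bp). Of the 3147 genes that lost PCAF with Activin-A, 692 (22.0%) were marked with dorsomorphin. They included Ms4a6b (1811 bp), Gimap5 (1956 bp), Cd53 (1147 bp), Tgfbr2 (744 bp), Cd69 (831 bp), Smad3 (533 bp), Gapdh (340 bp), Cab39 (370 bp) and Foxo3 (316 bp). In all, 938 genes gained and 784 lost a gene-end PCAF peak with dorsomorphin, 20 and 15 of them listed genes. The losses included the signalling genes Jak2 (1019 bp with Activin-A), Stat3 (493 bp), Il6ra (563 bp), Spred2 (1826 bp) and Foxo1 (572 bp), and Il10 (301 bp). By peak, 65.6% of PBS PCAF peaks had no Activin-A peak (64.7 to 66.5) and 14.7% of Activin-A peaks had no PBS peak (13.7 to 15.8). Dorsomorphin peaks stood at 18.9% (18.0 to 19.8) of lost, 23.8% (20.6 to 27.4) of gained and 70.6% (69.1 to 72.1) of shared PCAF regions. The median PCAF peak was 417 to 427 bp wide in all 3 libraries.

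The last comparison set PCAF beside H3K9ac. PCAF peaks overlapped an H3K9ac peak of the same arm at 80.4% with PBS (79.6 to 81.2), 80.0% with Activin-A (78.7 to 81.2) and 76.2% with dorsomorphin (74.9 to 77.4). Shifted positions gave 3.38%, 3.38% and 2.74%. The overlap was not particular to the arm. PCAF peaks of the Activin-A and dorsomorphin libraries overlapped H3K9ac peaks of the PBS library of experiment 1 at 81.15% and 80.72%. H3K9ac peaks of the PBS library lacked an Activin-A peak at 3.96% (3.53 to 4.44) of 7042 peaks with PCAF and at 26.4% (25.8 to 26.9) of 24920 peaks without it. Peaks with PCAF were wider, with a median of 3250.5 bp against 995 bp, so the shares were compared within width quartiles. From narrow to wide the shares with and without PCAF were 45.6% and 49.6%, then 25.7% and 28.6%, then 3.64% (2.88 to 4.60) and 8.37% (7.71 to 9.09), and 0.37% and 0.79%. Only in the third quartile did the intervals lie apart, and there peaks with PCAF were still wider (median 1962 against 1738 bp). Kat2b, the PCAF gene (chromosome 17, 53566774 to 53672721), was marked by H3K9ac and by PCAF in every library.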

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

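The test of the smallest gap in experiment 1 and those of joined peak numbers, in experiment 2 and in the dorsomorphin library, were chosen after the result was seen, and the other tests here before.

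Activin-A went with opposite differences in the 2 experiments. The H3K9ac peak number differed from PBS by 2270 in experiment 1 and by -4116 in experiment 2. Covered length differed by 0.43 and -6.54 Mb, and median width by -88 and 44 bp. With 1 library per arm in each experiment, the difference between the experiments was not tested.

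The opposite signs in peak number were weighed first. Different joining of neighbouring peaks is argued against, because the smallest gaps of the 2 libraries of experiment 1 differed by 20 bp (962 and 982 bp), and because joining within 1100 bp left a difference of -3506 in experiment 2. A difference in depth or calling threshold may account for it: peaks missing from the partner library were narrow, with an unshared share at least 49.47 times as high in the narrowest as in the widest width quartile. That ratio was also 90.05 and 182.38 for the libraries with fewer peaks, so it does not separate depth from true differences at weak sites. A biological difference between the experiments stays open and was not tested.

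The dorsomorphin H3K9ac library had more peaks and less covered length than its Activin-A partner. Joining may account for the peak number, which went from 35767 to 29606 after common joining, below the 33634 of the Activin-A library. It does not account for the covered length, which stayed at 0.80 of that of the Activin-A library. Depth and an effect of dorsomorphin cannot be separated for the rest with 1 library.

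The PCAF lists of both Activin-A libraries were short. A lower depth or yield of the precipitation may account for this, since PBS peaks missing with Activin-A were 2.28 times as frequent in the narrowest as in the widest width quartile. Even in the widest quartile 38.0% were missing, so narrow peaks are not the whole loss. In the reverse direction, 25.77% of Activin-A PCAF peaks in the narrowest quartile and 2.79% in the widest lacked a PBS peak. Narrow peaks were thus more often unshared either way, and the contrast by width does not separate lower depth from a true loss. A link with lower acetylation cannot be told apart from no link: at lost PCAF regions the share with H3K9ac was 4.21 points lower with Activin-A than with PBS, against 1.73 points at kept regions, which lies between the bounds set beforehand. A true loss of PCAF stays open.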

How the results depend on the processing

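Tests with an equal number of widest peaks, joining within 1100 bp, peaks of at least 500 bp and no overlapping peak, and all of the limma model, were chosen after the result was seen. For the results that answer a comparison, 88 values were unmoved, 97 moved and 5 reversed. A share was unmoved if it stayed inside its Wilson interval, which covers counting error only. A count was unmoved within 1.5 times the reported count. A difference in peak number or covered length was unmoved if it kept its sign and shifted by less than the SD between libraries. For the other results, single genes, loci and gene lists, the counts were 1574 unmoved, 530 moved, 31 now past the threshold and 3 no longer past it. Where nothing else is said, the cause was not tested. Depth is unknown and limits all of these values. Alternatives that needed a peak score were not run.

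All 5 reversals came from leaving out libraries, by construction fewer samples. The difference in peak number ranged from -4116 to 2270 (2270 without experiment 2 and 2162.5 without Activin-A 2). The difference in covered length ranged from -13.6 to 7.46 Mb (0.436 without experiment 2, 3.97 without PBS 1 and 7.46 without Activin-A 2). Lost regions ranged from 1450 to 7251, gained regions from 1167 to 8727, lost listed genes from 7 to 16 and gained listed genes from 1 to 10. The limma calls ranged from 21 to 153 lower and from 15 to 36 higher.

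With an overlap of 50% of the shorter interval, 3 listed genes were lost. PBS peaks unshared were 23.9% in experiment 1, 30.6% in experiment 2 and 66.6% for PCAF. Lost regions held a knockout peak at 28.5%. PCAF peaks on H3K9ac were 78.0%, 77.5% and 67.8% for PBS, Activin-A and dorsomorphin, and H3K9ac loss without PCAF was 29.4%.

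With the widest 50% of peaks, by construction fewer, 372 regions were lost, 184 gained and 3 listed genes lost. PBS peaks unshared were 13.7%, 20.9% and 68.2%, and lost regions held a peak at 29.8% (dorsomorphin) and 39.5% (knockout). PCAF peaks numbered 5063, 2079 and 2267, on H3K9ac at 85.6%, 82.0% and 78.8%, and H3K9ac loss without PCAF was 16.8%.

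With equal numbers of widest peaks, 2 listed genes were lost and PBS peaks unshared were 22.5%, 21.9% and 46.2%. Lost regions held a dorsomorphin peak at 20.5%, a knockout peak at 25.8% and, for PCAF, a dorsomorphin peak at 28.1%. PBS PCAF peaks lay on H3K9ac at 91.7%, and H3K9ac loss was 2.72% with and 25.3% without PCAF.

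With peaks of at least 500 bp, 3 listed genes were lost and 1 gained, and PBS peaks unshared were 20.2%, 24.1% and 70.7%. Lost regions held a dorsomorphin peak at 13.4%, a knockout peak at 32.6% and, for PCAF, a dorsomorphin peak at 17.5%. PCAF peaks numbered 3785, 1415 and 1558, on H3K9ac at 92.3%, 89.4% and 85.6%. H3K9ac loss was 2.42% with and 22.6% without PCAF, and limma called 1 lower and 1 higher locus.

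Joining within 500 bp gave 27.9% of PBS peaks unshared in experiment 2. Joining within 1100 bp gave 25.7% there and 64.5% for PCAF, and 1 lower locus by limma. Without centring limma again called 0 loci either way, with 247 at an unadjusted p under 0.05, and of the lists only the activin and TGF-β call ended. Without a flank limma called 2 lower loci. A gene-end window of 2000 bp gave 2 lost and 1 gained listed genes, gene bodies with 10 kb 2 and 2, and the demand for no overlapping peak 3 lost. The block on the experiment gave 11897 lost and 10415 gained regions and 21 lost and 12 gained listed genes, which by construction need a change in 1 experiment only, and it changed no call of limma and, of the lists, only the neuronal and the activin and TGF-β call.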

Other observations

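All values here were chosen after the result was seen. The widest H3K9ac domain covered Dad1 in all 6 libraries (chromosome 14, 54161329 to 54239880 on mm10, 78552 bp with PBS in experiment 1). Domains here hold joined neighbouring peaks. With PBS in experiment 2 the widest domain was 79636 bp and the widest deposited peak 71025 bp. Ranks and widths of domains therefore need not be those of the deposited peaks. Dad1 lies next to the locus of the T cell receptor alpha chain. Among the other wide domains, chosen here as examples, were those over Cd5 and Cd6 (70818 bp), Ets1 (59812 bp), Ptprc, which encodes CD45 (55208 bp), and Ikzf1 (39615 bp) in the same library. The order below Dad1 varied between libraries. In the Activin-A library of experiment 2 Ets1 stood at rank 3 (60249 bp) and Cd5 at rank 11 (26487 bp), and Ptprc and Ikzf1 were not among the 12 widest.

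Regions found in 1 library only numbered 3318 for the Prkaa1 knockout, and 611 were absent from the knockout alone. Within 5 Mb of Prkaa1, 10 of 114 regions occurred in the knockout only (8.77%, against 6.32% of all regions).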
